A study of Rattus norvegicus with 6 samples.

How the data were processed

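The series profiled the messenger RNA of primary rat (Rattus norvegicus) ovarian granulosa cells, the follicle cells that surround the oocyte and make oestradiol from androgen. Per the series' design text, the rats were 21 days old, were injected with PMSG (equine serum gonadotropin, a hormone that stimulates follicle growth) at 60 IU, and their ovaries were taken 48 h later for enzymatic dispersal and culture of the cells. Total RNA was extracted with Trizol, poly(A) RNA was selected with oligo(dT) beads, and random-primed libraries were read as pairs of 150 bases on an MGI2000, per the labels' protocols. No strand-marking step is described there. The titles place 3 libraries in a group called ATR and 3 in a group called Control. The series' title concerns long exposure to atrazine, a triazine herbicide, but no label used here spells out ATR. The dose, the length of exposure, and whether animals or cultured cells were exposed are not given in the sources used here.

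The columns available for this work belong to the 3 ATR libraries. The 3 Control libraries are not analysed here, so the planned contrast of ATR against Control, its gene list tests of fold changes and its fold-based naming of genes were not run. What follows describes the levels in the ATR libraries and the spread between them, and no value below is an effect of an exposure. The measures, tests and settings that replaced the planned contrast were chosen after the table's columns had been seen, while the gene lists were fixed before the data were examined.

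For each gene and library the authors deposited a TPM value (expression scaled for transcript length and library size) and an estimated count of reads, per the file headers. The submitters' processing notes name fastp 0.20.1, HISAT2 2.2.1 and StringTie 2.1.5 without saying which value each tool made. Those notes name the rat build Rnor_6.0 and the mouse build GRCm38. The gene identifiers are those of rat genes, since 16392 of 17525 (93.5%) were found in a rat RefSeq gene table of assembly GRCr8, which was used for names alone. No coordinates are given because the builds differ. All 17525 rows are typed as mRNA, and each has reads in at least 1 ATR library. The deposited TPM values sum to about the same total in each library over these rows. The authors deposited the estimated counts with library totals that differ, and 19.0% to 19.2% of these values in a library lie more than 0.001 from a whole number. How reads were divided between genes is not given in the sources used here. The ratio of count to TPM, which follows transcript length, had a median coefficient of variation between libraries of 0.0778% over 10004 genes above 5 TPM. It exceeded 5% in 178 of them.

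The estimated counts were rounded to whole numbers. Libraries were scaled with the TMM method of edgeR 4.0.16 (R 4.3.3), which also gave the common biological coefficient of variation from an intercept-only model after filterByExpr with a minimum count of 10. Spread beyond counting noise was tested per gene with a chi-square test of the 3 counts against the scaled library sizes. That test took genes with at least 30 reads in all, with Benjamini-Hochberg adjustment and a threshold of 0.05. It compares these libraries and not conditions, and because molecules carry no identifiers it counts duplicated reads as independent. On simulated counts drawn from the real means with no extra spread, it recovered 84.0% of 100 genes raised 1.5-fold in 1 library and 91.0% of 100 genes raised 2-fold. It made 7 false calls among the 13306 genes run. Read ratios between libraries carry exact (Clopper-Pearson) 95% intervals that cover counting error only.

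The 24 gene lists covered pathways of the ovary, of toxicant response and of fibrosis, and markers of the other cell types an ovarian culture could hold. Of 603 entries, 581 were found, 9 of them through the gene identifier because the table uses an older symbol. A list's level was summarised as the median of its members' mean TPM and placed among 10000 random lists of the same size. Its spread was summarised as the median standard deviation of log2(CPM + 0.5), where CPM is reads scaled to library size, over members with a mean of at least 1 CPM. The spread was placed among 10000 random lists matched on mean expression in 20 bins. In the simulation a planted list of 20 genes raised 2-fold in 1 library lay above all random lists, and 1 of 200 lists without planted change lay in the upper 2.5%. Simulated genes were independent and had no extra spread. Their median chi-square per degree of freedom was 0.69, against 1.69 in the real counts. The simulation therefore gives no rate of false calls for the real lists. Genes of a list are not independent, so these percentiles describe these libraries and are not p-values. Lists made of well-known genes also tend to be better expressed than random ones. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

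Named genes are the 8 with the highest mean TPM and a gene symbol, up to 4 list members with the highest mean TPM per list, and the genes fixed beforehand (Fshr, Cyp19a1, Star, Col1a1, Fn1, Acta2, Tgfb1, Ctgf, Il6, Il1b, Tnf and Cyp1a1). The first and second parts replace the fold-based rule. Other genes were chosen after their values were seen. The libraries held 19020494, 18677212 and 19170552 reads assigned to genes, and a count of 0 allows up to 0.156 to 0.161 CPM, from 3 reads, for counting error only. The alternatives were other detection limits, other scalings and filters, other units and backgrounds for the lists, and each library left out in turn.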

Results

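Messenger RNA was measured in primary rat ovarian granulosa cells of the ATR group, in 3 libraries called ATR 1, ATR 2 and ATR 3. The libraries held 19020494, 18677212 and 19170552 reads assigned to genes. The Control group's 3 libraries are not analysed here, so the comparison the design implies, ATR against Control, has no value below. The series' title names ovarian dysfunction, an inflammatory microenvironment and fibrosis after atrazine exposure, and the levels of genes tied to these themes are given for the ATR cells alone. Errors are SDs over the 3 libraries. The labels do not say whether these came from separate animals or cultures, so the spread may be technical. They do not spell out ATR either.

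The most abundant transcript was that of Tagln (transgelin, an actin-binding protein of smooth muscle and myofibroblasts), at 10890 ± 415 TPM (SD, n = 3). It was followed by Actb at 8742 ± 146, Tmsb4x at 7816 ± 334, Actg1 at 6375 ± 149, Sparc (a matrix glycoprotein) at 6264 ± 103 and Acta2 (smooth muscle actin) at 5496 ± 311 TPM. Eef1a1 stood at 5028 ± 345 and S100a6 at 4093 ± 463 TPM. The counts of Actb, Actg1 and Acta2 are not whole numbers, so reads of these similar genes can be shared between them and their single levels are uncertain. A mean of at least 1 TPM was reached by 12518 of the 17525 genes, and at least 1000 TPM by 154. The 10 genes with the most reads took 6.63% to 6.82% of each library.

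Matrix and fibrosis genes were expressed at high levels. Of 40 measured members of that list, 38 reached 1 TPM and 26 reached 100 TPM, with a median of 452 TPM that lay above all 10000 random lists. Together they held 5.32% ± 0.0163 of all TPM. Beside Tagln, Sparc and Acta2, the leading members were Fn1 (fibronectin) at 3823 ± 177 and Thbs1 at 3607 ± 143 TPM. Ctgf, the connective tissue growth factor now named Ccn2, stood at 3569 ± 108, and Col1a1 (collagen I alpha 1) at 2885 ± 252 TPM. Serpinh1, a collagen chaperone, was at 2089 ± 36.1 TPM and the cross-linking enzyme Lox at 614 ± 58.4 TPM. The matrix proteases differed widely: Mmp14 stood at 465 ± 13.6 and Mmp2 at 38.1 ± 17.3 TPM, while Mmp9 had 0, 2 and 1 reads. The second chain of collagen I, Col1a2, varied more than Col1a1, with 287, 801 and 601 TPM in ATR 1, ATR 2 and ATR 3. The Col1a1 to Col1a2 ratio was accordingly 9.03, 3.82 and 4.99, and Col1a2 counts are not whole numbers. Another row, NEWGENE_621351, also had counts that are not whole, at 92.6, 251 and 163 TPM, with the same order of libraries. If that row took reads of Col1a2, the level of Col1a2 is understated and these ratios are too high. The ratios are therefore uncertain as a balance of the 2 chains.

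**Figure D1:**
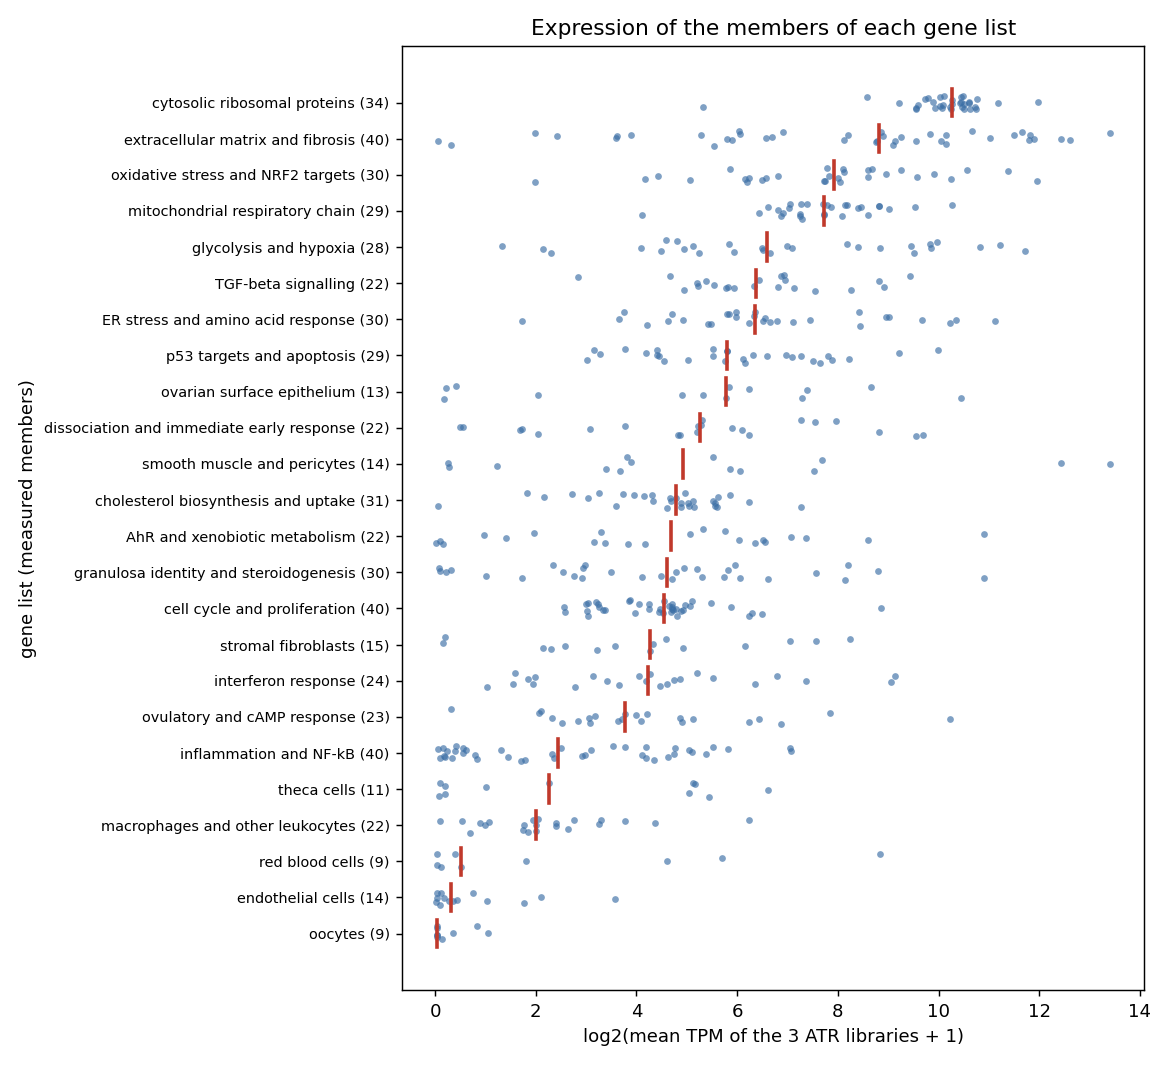
Each point is the mean level of 1 gene over the 3 ATR libraries, on a log2(TPM + 1) axis, and each red bar is the log2 of a list's median TPM + 1, with the number of measured members in brackets. Ribosomal protein genes had the highest median (1224 TPM), followed by matrix and fibrosis genes (452 TPM), and oocyte genes the lowest (0.030 TPM).

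All 22 measured genes of TGF-beta signalling, the main profibrotic growth factor pathway, reached 1 TPM, with a median of 82.3 TPM. Tgfb3 was the most abundant ligand at 690 ± 84.8 TPM, followed by Tgfb2 at 482 ± 43.2 and Tgfb1 at 111 ± 8.52 TPM. Tgfb3 exceeded Tgfb1 by 7.67, 5.20 and 5.99 times in the 3 libraries. Id3, a target of BMP and TGF-beta receptors, stood at 451 ± 49.6 and the latent binding protein Ltbp2 at 304 ± 16.2 TPM.

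The inflammation and NF-kB list was much lower, with a median of 4.41 TPM, at percentile 9.83 of random lists. It lay at 3.56 among random lists matched on implied transcript length, and at 1.78 with genes above 0.1 TPM alone as background. Of its 40 measured members, 26 reached 1 TPM and 2 reached 100 TPM: the interleukin-1 receptor Il1r1 at 133 ± 7.91 and the macrophage growth factor Csf1 at 132 ± 14.98 TPM. Icam1 followed at 55.8 ± 6.78 and Lif at 45.2 ± 4.91 TPM. The classical cytokines were near the counting limit. Il6 had 2, 3 and 0 reads, Il1b 3, 1 and 1 reads, and Tnf 1, 1 and 3 reads. The chemokines Ccl2 at 33.3 ± 17.3 TPM and Ccl7 at 31.8 ± 16.1 TPM were present and had larger SDs relative to their means than the members above them. Among interferon-response genes all 24 measured members reached 1 TPM, led by Ifi27 at 562 ± 104, B2m at 532 ± 8.195, Bst2 at 165 ± 39.9 and Ifitm3 at 109 ± 9.42 TPM.

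Granulosa cell genes fell into a well-expressed and a nearly silent part. Of 30 measured members of the granulosa and steroidogenesis list, 26 reached 1 TPM and 5 reached 100 TPM, with a median of 23.3 TPM. The most abundant were Gja1 (connexin 43, the gap junction protein of granulosa cells) at 1906 ± 114, Inha (inhibin alpha) at 443 ± 73.0, Igf1 at 292 ± 32.2 and Inhba at 282 ± 1.92 TPM. The transcription factors Gata4 (189 ± 14.2 TPM), Nr5a1 (60.9 ± 1.72 TPM) and Foxl2 (55.1 ± 7.88 TPM) were expressed. Star, which brings cholesterol into mitochondria, stood at 97.3 ± 17.8 TPM. Fshr, the receptor for follicle-stimulating hormone that the submitters stained to identify the cells, was at 5.80 ± 1.39 TPM and ranked 9995 among the 17525 genes, from 155, 111 and 103 reads. Cyp11a1, which makes pregnenolone, was at 1.02 ± 0.270 TPM. Cyp19a1 (aromatase, which makes oestradiol) had 1, 1 and 2.33 estimated reads, and the luteinizing hormone receptor Lhcgr 5, 3 and 4 reads. Of the 3-beta-hydroxysteroid dehydrogenases, whose copies are similar enough to share reads, Hsd3b3 stood at 18.98 ± 1.29 TPM and Hsd3b6 at 4.85 ± 0.455 TPM.

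**Figure D2:**
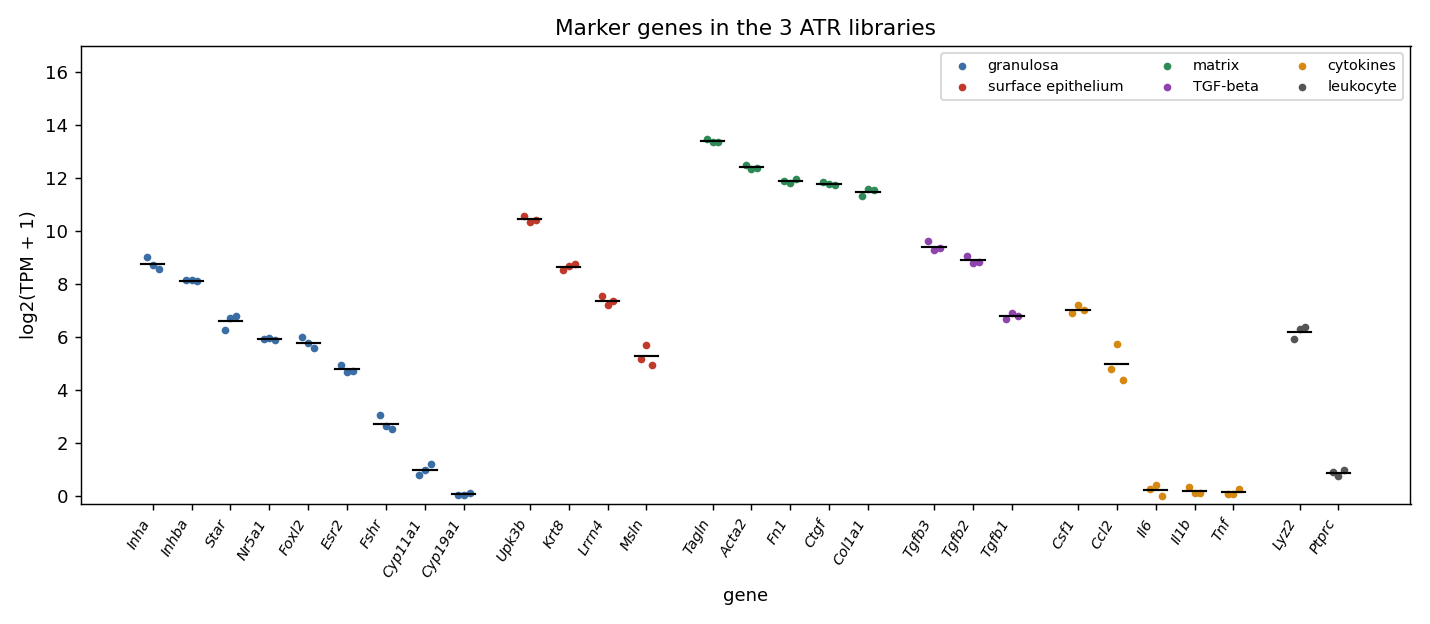
Points are the TPM values of ATR 1, ATR 2 and ATR 3 (left to right within a gene) on a log2(TPM + 1) axis, black bars are their means on that axis, and colours mark the kind of gene. Upk3b (1403 TPM) and the matrix genes lie far above Fshr (5.80 TPM), while Cyp19a1, Il6, Il1b and Tnf lie near 0.

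Genes of the ovulatory and cAMP response were expressed in 22 of 23 cases at 1 TPM or more, with a median of 12.6 TPM. Rgs2 led at 1198 ± 114 TPM, followed by Adamts1 at 230 ± 17.3 and Tnfaip6 at 117 ± 1.63 TPM, whereas Pgr (the progesterone receptor) stood below 1 TPM.

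Markers of other ovarian cell types differed strongly in level. Of 13 surface epithelium markers, 10 reached 1 TPM and 9 reached 10 TPM, with a median of 54.2 TPM at percentile 99.63 of random lists, or 97.21 when CPM was ranked in place of TPM. Upk3b, a uroplakin of mesothelium, stood at 1403 ± 101 TPM, Krt8 at 405 ± 28.0, Lrrn4 at 167 ± 20.4 and Krt18 at 156 ± 16.0 TPM, but Krt19, Epcam and Muc16 stayed below 1 TPM. In each library Upk3b exceeded Fshr by at least 205 times. Stromal fibroblast markers had a median of 18.2 TPM, led by Col14a1 at 301 ± 33.2, Ogn at 188 ± 13.6 and Gsn at 132 ± 4.86 TPM, with Pdgfra at 3.43 ± 1.97 TPM. The smooth muscle list, which shares Acta2 and Tagln with the matrix list, had a median of 29.3 TPM. In it Mcam stood at 204 ± 16.7 and Cnn1 at 183 ± 16.9 TPM, but the pericyte gene Notch3 was at 1.34 ± 0.0929 TPM. Leukocyte markers had a median of 3.02 TPM, with Lyz2 at 74.0 ± 12.1, Cd14 at 19.5 ± 2.08 and Cd68 at 12.7 ± 1.91 TPM, and the pan-leukocyte gene Ptprc below 1 TPM. Theca cell markers had a median of 3.80 TPM, and Cyp17a1, the androgen-making enzyme of theca cells, had at most 3.63 estimated reads in a library. Endothelial markers had a median of 0.238 TPM, red cell markers one of 0.423 TPM and oocyte markers one of 0.030 TPM.

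Stress and xenobiotic genes were broadly expressed. All 30 NRF2 and antioxidant genes reached 1 TPM, and 20 reached 100 TPM, with a median of 241 TPM. Their leaders were the ferritin genes Ftl1 (3958 ± 223 TPM) and Fth1 (2666 ± 206 TPM), Txn1 (1516 ± 96.9 TPM) and Prdx1 (1222 ± 22.4 TPM). Of the 22 measured genes of the AhR and xenobiotic list, 18 reached 1 TPM, with a median of 24.7 TPM. Gstp1 (glutathione transferase) stood at 1910 ± 166, Ephx1 at 389 ± 24.1 and Cyp1b1 at 165 ± 38.1 TPM, against 7.97 ± 4.03 TPM for Cyp1a1, the most familiar AhR target. All 29 measured p53 targets and apoptosis genes reached 1 TPM, with a median of 54.7 TPM, led by the cell cycle inhibitor Cdkn1a at 1011 ± 47.9 and by Ccng1 at 590 ± 17.5 TPM. All 30 endoplasmic reticulum stress genes did so too, with a median of 80.6 TPM, led by the chaperones Calr at 2217 ± 36.2 and Hspa5 at 1302 ± 98.1 TPM, with Ddit3 at 61.8 ± 3.98 TPM. Immediate early and dissociation genes had a median of 37.2 TPM and were led by Hspb1 at 831 ± 4.03 and Hsp90aa1 at 755 ± 42.9 TPM, while Fos stood at 7.41 ± 0.280 TPM.

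Proliferation and metabolic genes were measured in every library. All 40 cell cycle genes reached 1 TPM, with a median of 22.3 TPM. Ccnd2, the granulosa cyclin D, was the only member above 100 TPM, at 460 ± 20.6, followed by Pcna at 89.0 ± 8.77 and Rrm2 at 77.4 ± 9.97 TPM, with Mki67 at 13.4 ± 3.67 TPM. The 29 respiratory chain genes had a median of 210 TPM, led by Atp5b at 1231 ± 20.8 TPM. The 28 glycolysis and hypoxia genes had a median of 95.3 TPM, led by Gapdh at 3376 ± 86.7 and Pkm at 2380 ± 106 TPM. Cholesterol synthesis and uptake genes had a median of 26.4 TPM, led by Fdps at 154 ± 8.44 TPM. Cytosolic ribosomal protein genes held 4.32% ± 0.211 of all TPM.

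The 3 libraries resembled each other closely but were not one library deposited again. Pearson correlations of log2(TPM + 1) across genes, which are not independent replicates, were 0.994 to 0.995. The median coefficient of variation was 6.16% among genes at 1 TPM or more, and edgeR gave a common biological coefficient of variation of 8.23%. The chi-square test found spread beyond counting noise in 3089 of 13309 genes (23.2%), and each pair of libraries differed in 1525 to 2225 genes. Of 10506 genes with a mean of at least 5 CPM (reads scaled to library size), 86 differed by 2-fold or more between ATR 1 and ATR 2, 67 between ATR 1 and ATR 3, and 49 between ATR 2 and ATR 3.

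Of the 24 lists, 13 had a spread between libraries in the upper 2.5% of matched random lists, and 11 lists no longer did with some library left out, at percentiles from 6.51 to 97.28. Interferon-response genes had the largest median SD of them. Of 24 members, 20 were highest in ATR 1, and 21 passed the chi-square threshold. Relative to each gene's mean, the list's median log2 deviation was 0.53 in ATR 1, -0.25 in ATR 2 and -0.21 in ATR 3. Usp18, a deubiquitinase induced by interferon, stood at 13.1 TPM in ATR 1 and at 2.49 and 1.95 TPM in the others, a read ratio of ATR 1 to the other libraries pooled of 5.76 (95% interval 4.30 to 7.80). The antiviral GTPase Mx2 had a ratio of 4.805 (4.22 to 5.48), Isg15 one of 2.06 (1.85 to 2.30) and Irf7 one of 2.25 (2.03 to 2.496). B2m had a ratio of 0.968 (0.943 to 0.993) and Psmb8 one of 0.981 (0.838 to 1.15). The list's median SD of 0.46 on the log2 scale lay above all 10000 matched random lists, and at percentile 80.52 without ATR 1. ATR 1 stood apart in other lists too. Ribosomal protein genes were lowest there for 31 of 34 members, with a median log2 deviation of -0.11, and their spread fell from percentile 100 to 6.51 without ATR 1. Of 25 inflammation genes with a mean of at least 1 CPM, 16 were lowest in ATR 1 (median log2 deviation -0.10) and 16 were highest in ATR 2 (0.08), and their spread lay at percentile 59.58 without ATR 1.

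Cell cycle genes were highest in ATR 3 for 36 of 40 members and lowest in ATR 2 for 27, with median log2 deviations of -0.04, -0.14 and 0.21 in ATR 1, ATR 2 and ATR 3. Of the 40 members, 28 passed the chi-square threshold. Mki67 stood at 13.5, 9.63 and 16.97 TPM and Ccnd1 at 16.7, 28.1 and 43.0 TPM. The list's spread lay above all matched random lists, and at percentile 96.19 without ATR 3.

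A part of the stromal list was lowest in ATR 1. Thy1, a fibroblast surface antigen, stood at 23.2, 104 and 82.7 TPM in ATR 1, ATR 2 and ATR 3, a read ratio of ATR 2 to ATR 1 of 4.64 (4.12 to 5.25). Prrx1, a mesenchymal transcription factor, had a ratio of 3.92 (3.29 to 4.68) and the receptor Pdgfra one of 4.04 (3.15 to 5.23). Other members went the other way or were level, with ratios of 0.819 (0.802 to 0.837) for Col14a1, 0.906 (0.870 to 0.944) for Ogn and 0.921 (0.790 to 1.07) for Dcn. NRF2 and antioxidant genes were lowest in ATR 1 for 22 of 30 members and highest in ATR 2 for 20, by small margins, with median log2 deviations of -0.06 in ATR 1 and 0.06 in ATR 2. Nqo1, a quinone reductase, stood at 567, 985 and 726 TPM in ATR 1, ATR 2 and ATR 3.

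**Figure D3:**
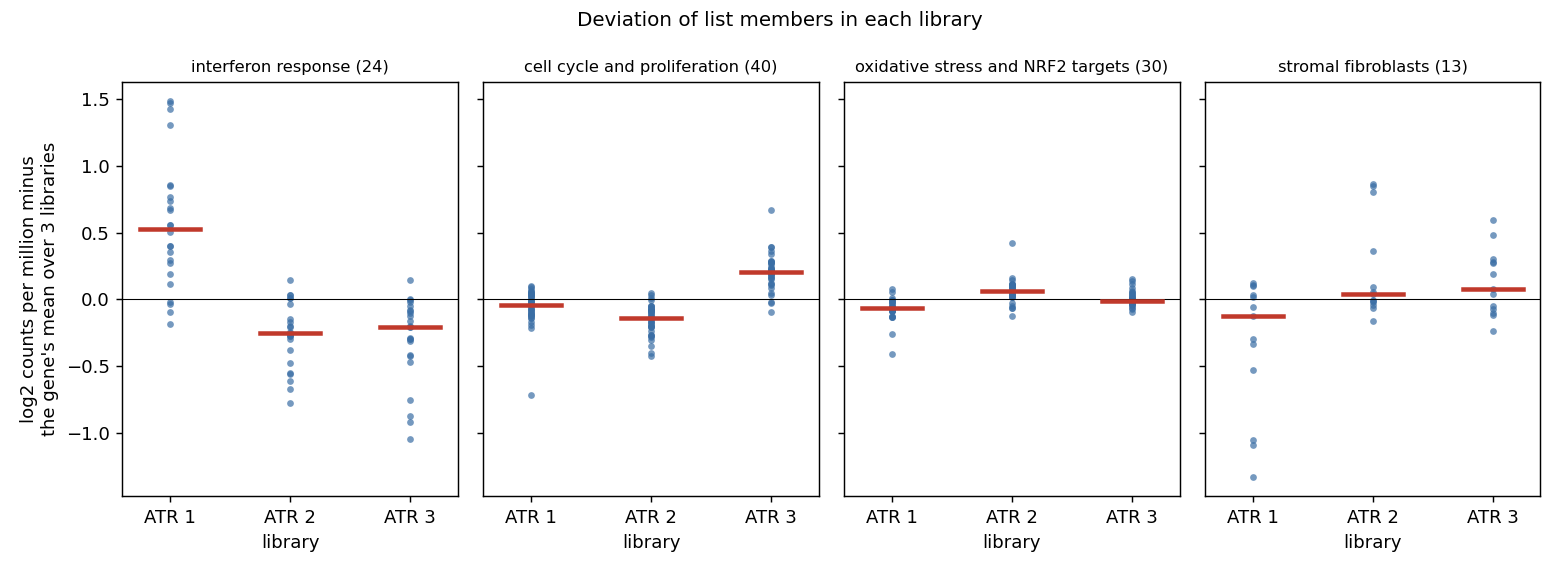
Each point is 1 list member with a mean of at least 1 CPM in 1 library, as its log2 CPM minus the gene's mean over the 3 libraries, and red bars are list medians. Interferon genes lie highest in ATR 1 (median 0.53) and cell cycle genes in ATR 3 (median 0.21), and stromal genes spread in both directions.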

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

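No paired analysis was possible because the columns used here belong to the ATR group alone, and none of the alternatives planned for the contrast with Control was run. All alternatives here were chosen after seeing the data. The count of genes at 1 TPM or more stayed within 1.5 times of 12518 under the other limits tried, from 10265 genes at a mean of 5 TPM to 13327 at 0.5 TPM. The count of genes varying beyond counting noise was 3089. It was 3167 with library totals and 2127 among genes with whole read counts alone, and between 1525 (without ATR 1) and 2225 (without ATR 3) with 1 library left out, where a test on fewer libraries has less power. The common biological coefficient of variation of 8.23% ranged from 6.91% without ATR 1 to 9.69% without ATR 3, and was 9.25% without a low-count filter. Matrix genes lay above all random lists under each alternative tried. So did the NRF2, ribosomal protein, endoplasmic reticulum stress, respiratory chain and glycolysis lists. The inflammation list moved from percentile 9.83 to 1.78 when genes above 0.1 TPM alone were the background. The interferon list's spread lay at percentile 80.52 to 100 with 1 library left out, the lowest without ATR 1, and the cell cycle list's at 96.19 to 100, the lowest without ATR 3. The stromal list's spread stayed in the upper 2.5% under each alternative. With a library left out, 11 of the 13 lists in the upper 2.5% for spread left it, 8 of them without ATR 1, at percentiles from 6.51 (ribosomal proteins, without ATR 1) to 97.28 (ovulatory response, without ATR 2). At 18677212 to 19170552 reads per library, genes with a few reads per library, such as Il6 and Cyp19a1, cannot be ranked against each other.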

Other observations

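The tests of scaling, of leukocytes, of stromal cells and of surface epithelium in this part were chosen after the values had been seen. The rules on transcript length were written before those tests were run, but for patterns found in these same values. No biological explanation was tested against a group, since 1 group was analysed. The bootstrap intervals below treat list members as independent, which they are not. They cover spread between genes and not between libraries.

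The genes outside the lists that are named in this paragraph were chosen after their values were seen. Among 129 genes, list members included, with a mean of at least 5 CPM, spread beyond counting noise and an SD above 0.5 on the log2 scale, 53 stood furthest from the mean by being low in ATR 1 and 39 by being high in ATR 2. The proteoglycan Acan stood at 16.0, 108 and 54.8 TPM in ATR 1, ATR 2 and ATR 3. Mgp (matrix Gla protein) stood at 61.5, 240 and 51.7 TPM, Prelp at 21.2, 93.9 and 28.3 TPM, and the BMP antagonist Grem1 at 51.6, 162 and 85.1 TPM. The cyclooxygenase Ptgs1 stood at 9.21, 57.1 and 29.2 TPM. The AhR and xenobiotic list was highest in ATR 2 for 13 of 18 members, among them Cyp1a1 at 6.14, 12.6 and 5.18 TPM and Cyp1b1 at 134, 207 and 152 TPM.

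Of the alpha globin genes, the one the file calls Hba-a1 (now Hba-a3) stood at 457 ± 69.5 TPM, Hba2 at 51.0 ± 13.1 TPM and Hba1 (now Hba-a1) at 23.3 ± 0.541 TPM. Their counts are not whole, so reads of these similar genes can be shared and their single levels are uncertain. The beta globin gene Hbb had 1, 1 and 3 reads and the erythroid enzyme gene Alas2 0, 0 and 1 reads. Some genes had nearly all their reads in 2 libraries: Fam134b had 299.6, 295.8 and 0.01 estimated reads, and Vwa5a 682, 742 and 22.5. Wbp11l1 had 632, 631.74 and 0.08 estimated reads, while Wbp11 went the other way in ATR 3, with 803, 740.26 and 1457.92. The counts of these genes are not whole, so reads may be shared with similar genes. Vwa5a had 682.31, 742.49 and 22.49 estimated reads, against 132.69, 150.51 and 874.51 for the row LOC108348048. Their decimals complete each other to whole numbers, as those of Wbp11l1 and Wbp11 do in ATR 2 and ATR 3. The other row rose in ATR 3 in both cases. This argues against a loss of expression of Vwa5a and Wbp11l1 in ATR 3. For Fam134b no such row is given here, and its low value in ATR 3 need not mean low expression. Counts that are not whole were found for 39.5% of the 129 most variable genes and for 21.4% of all 10506 at that expression.

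Interferon genes were higher in ATR 1 than in the other libraries by a median of 0.79 on the log2 scale (95% bootstrap interval over 24 members 0.44 to 1.11). This list was singled out after its rise in ATR 1 had been seen, so its percentile of 100 among matched random lists was settled in advance. The median over all genes with a mean of at least 1 CPM was -0.00023. TMM scaling holds this median near 0, so the value cannot test a scaling difference. The list's spread lay at percentile 100 with library totals in place of TMM too. The tables argue against transcript length, since the list's median was 0.80 after the trend on implied length was removed. More leukocytes in ATR 1 would raise the leukocyte list, which went the other way, by -0.18 (-0.46 to -0.09). Its most abundant gene, Lyz2, stood at 60.2, 78.6 and 83.2 TPM. Only 3 of the list's 20 tested members passed the chi-square threshold, and its median was 3.02 TPM. The list thus showed no rise in ATR 1 but cannot exclude a small difference in leukocytes. An interferon response in the cells behind ATR 1 is a candidate explanation that stays open, as does a batch that the labels do not record.

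Stromal genes were higher in ATR 2 than in ATR 1 by a median of 0.28 (0.01 to 0.48 over 13 members), at percentile 99.99 of matched random lists. That percentile is no separate test, because the pattern had been seen before. The median over all genes with a mean of at least 1 CPM was 0.00045, which TMM scaling again holds near 0. It cannot test a scaling difference either. The stromal list's spread lay at percentile 100 with library totals in place of TMM. After the trend on implied length was removed the stromal median was 0.27 (0.0086 to 0.46), so that trend accounted for little of it. The interval had begun at 0.01 before the removal, so its width cannot decide on length. A different share of stromal fibroblasts may contribute: 6 of 13 members had a ratio with an interval above 1, and 2 (Col14a1 and Ogn) had one below 1. Whether cell mixture or a change of state lies behind Thy1, Prrx1 and Pdgfra cannot be told apart, because other cells in the culture can supply the members that did not follow.

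Surface epithelium markers had a median of 54.2 TPM, at percentile 99.63 of random lists, and Gata4, Nr5a1 and Foxl2 stood at 189, 60.9 and 55.1 TPM. Surface epithelial or mesothelial cells in the culture are a candidate source. The test leaves this open: 3 of 13 members (Krt19, Epcam and Muc16) stayed below 1 TPM, and keratins and Wt1 can also be expressed by granulosa cells, though no member stands in another list, so bulk RNA cannot assign them to a cell.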
